A study of Mus musculus with 24 samples.

How the data were processed

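RNA from 24 formalin-fixed, paraffin-embedded CT26 tumours was measured on the NanoString nCounter Mouse PanCancer Immune Profiling panel, in which labelled probes are counted one molecule at a time without amplification. Per the labels' protocols, RNA came from 3 sections of 10 um per tumour, was brought to 20 ng/uL where possible, and 100 ng went into each hybridisation. Mice were randomised on day 7, at a mean tumour volume of about 50 mm3, and the tumours sampled were chosen to lie near the mean volume of their group. The p values below cover the spread between tumours chosen in this way, not that over all tumours of a group. The 24 tumours form 4 groups of 6, by treatment of the cells in culture and antibody given to the mice, as the labels give them. The labels name no batch.

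The authors deposited 1 table of 750 genes in 24 tumours, whose values are on a log2 scale. Each deposited log2 value was, within a tolerance of 0.05 of a whole count, a whole number multiplied by 1 factor per tumour, for 100% of values. These factors ran from 0.522 to 5.457, and the totals of the recovered counts from 62699 to 687032. The sources used here do not give the normalisation steps behind the factors. The table holds no rows marked as housekeeping genes or controls (0), so the factors could not be recomputed. Differences in log2 factor between the groups compared had exact permutation p values of 0.848 (anti-PD-1 against isotype, DMSO tumours), 0.961 (the same, NP1867 tumours), 0.489 (NP1867 against DMSO, isotype) and 0.478 (the same, anti-PD-1), two-sided. In a tumour with a large factor each count covers a wide step: 3 counts correspond to a log2 value of 4.03 in DMSO isotype tumour 23 and 0.65 in NP1867 anti-PD-1 tumour 48. None of the 276 pairs of tumours held identical counts (r from 0.842 to 0.984). Against a RefSeq gene table of the GRCm38.p6 assembly, used for names only, 736 symbols matched directly, 8 as older symbols and 6 not at all; Gpr44 and Ptgdr2 are 1 gene. B2m, Pms2 and Mb21d1, fixed as genes of interest, are not in the table.

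Genes with a mean of at least log2 of 20 over all tumours were tested, 600 genes; the other 150 were not. limma 3.58.1 in R 4.3.3 fitted the 4 group means to the log2 values of all 24 tumours, with 20 residual degrees of freedom and an empirical Bayes prior of 4.3 degrees of freedom with a mean trend. From this fit came 7 comparisons: anti-PD-1 against isotype in DMSO and in NP1867 tumours, NP1867 against DMSO under each antibody, the difference between the responses to anti-PD-1, and both effects averaged over the other factor. P values were two-sided, adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05. SEs are those of the fitted log2 fold change. A count of tumours above or below a mean sets each treated tumour against the mean of its control group.

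Before the data were examined, 30 gene lists were fixed from general knowledge of tumour immunology, of which 29 had at least 3 tested genes. Erythrocyte, skeletal muscle and skin markers had 0 genes in the table. Lists share genes. Each list was tested with limma's fry, which asks whether its genes move on balance one way and does not compare it with other genes, with adjustment over the lists. A list's score in a tumour is the mean log2 value of its tested genes. Alternatives to fry were camera with an estimated and with a preset correlation between genes, which compares a list with the other genes, and an exact permutation test of the scores over the 924 assignments of 6 against 6 tumours. The genes named were chosen by a rule fixed beforehand: for each simple comparison the 15 largest rises and 10 largest falls past the threshold, or the 10 genes with the lowest p where fewer passed; up to 4 members of each list that passed; a fixed set of immune genes; and the 5 genes with the lowest p in the other comparisons. The text gives values for some of these and counts the rest.

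The fit was tested on data simulated for anti-PD-1 against isotype in NP1867 tumours, in 20 runs of 600 genes with 200 changed. It called 36.7% of changes of 0.5 on the log2 scale, 79% of changes of 1 and 98.8% of changes of 2, with 1.8% false calls and 0 of the wrong sign. It found the T cell list in 9 of 20 runs, and lists called without a change occurred in 2 runs.

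The alternative settings fixed together with the lists were centring each tumour on its median, quantile normalisation, no filter, a filter at 50 (466 genes), a fit of only the groups compared, robust empirical Bayes, array weights, Ptprc as a covariate and each tumour left out in turn. Added after seeing the data were limma-voom on the recovered counts, the log2 scaling factor as a covariate, log2 total counts as a covariate, 10 added to the scaled counts before the logarithm, and a fit without the 4 tumours of fewer than 200000 counts. The count tools edgeR and DESeq2, planned in case whole counts could be recovered, were not used; limma-voom was fitted to the recovered counts instead. For each comparison 100 splits of its tumours were drawn, the real one included, and refitted. Correlations with Ptprc were taken within groups, with p values from 100000 permutations within groups. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the recovery of counts, the tables and the figures.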

Results

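Immune gene expression was measured in 24 subcutaneous CT26 tumours, grown in BALB/c mice from a mouse colon carcinoma line that arose in this strain. The cells had been cultured for 40 weeks with the PMS2 inhibitor NP1867 at 0.5 uM or with its solvent DMSO. PMS2 is a subunit of the MutLα complex of DNA mismatch repair. Mice bearing either kind of tumour received 4 doses of 5 mg/kg of an antibody against PD-1, an inhibitory receptor of T cells, or of an isotype control antibody. The tumours were taken on day 19, which was 24 hours after the last dose. Each of the 4 groups (DMSO isotype, DMSO anti-PD-1, NP1867 isotype and NP1867 anti-PD-1) held 6 tumours, and each tumour is 1 replicate, named here by the number in its sample title. The panel gave log2 values of 750 immune and cancer genes. The counts behind them summed to between 62699 in DMSO isotype tumour 23 and 687032 in NP1867 anti-PD-1 tumour 48. Mean totals per group were 287371 ± 174793 (SD, n = 6) for DMSO isotype, 333088 ± 179640 for DMSO anti-PD-1, 330362 ± 74928 for NP1867 isotype and 453852 ± 180402 for NP1867 anti-PD-1. The 4 tumours with fewer than 200000 counts were all DMSO tumours (isotype 6 and 23, anti-PD-1 11 and 37). Genes with a mean log2 value of at least log2 of 20 were tested, which left 600.

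**Figure D1:**
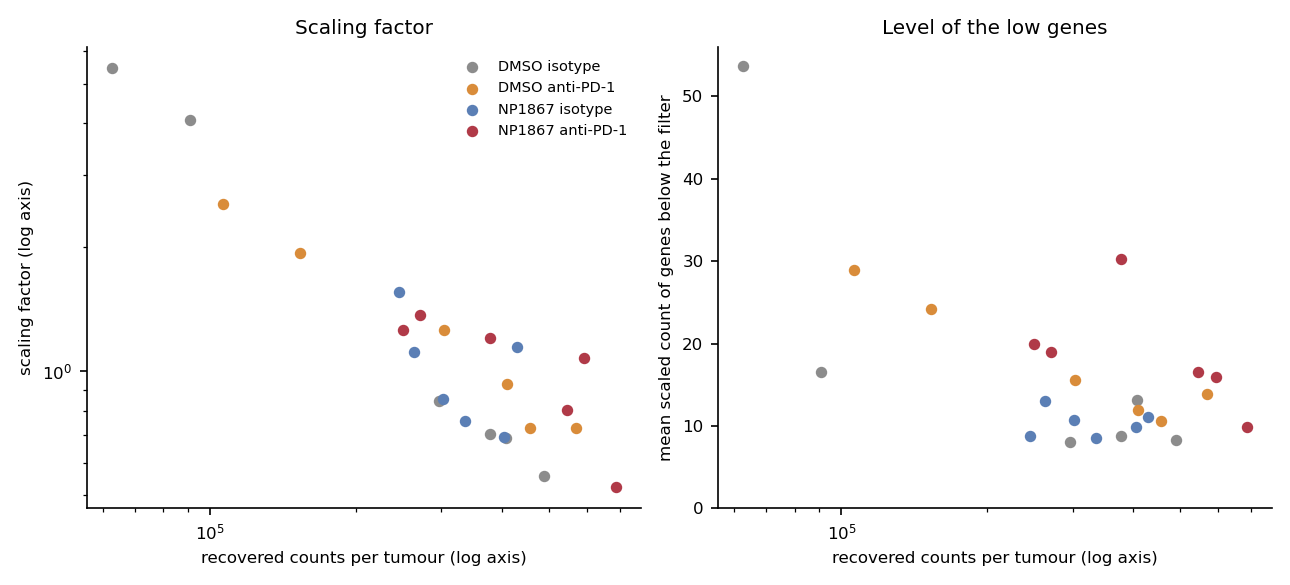
Recovered counts per tumour (x, log axis) against the scaling factor of that tumour (left, log axis) and the mean scaled count of the 150 genes below the expression filter (right). Each point is 1 of 24 tumours, coloured by group; DMSO isotype tumour 23, with 62699 counts and a factor of 5.46, has the highest scaled level of the low genes, 53.7.

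The first comparison asked what anti-PD-1 changed in tumours grown from NP1867-treated cells. Genes of antigen presentation to CD4 T cells rose most. H2-Eb1, a chain of the MHC class II molecule, rose 5.36-fold from a log2 value of 9.10 ± 0.89 to 11.52 ± 0.88 (SD, n = 6 per group; log2 fold change 2.42, SE 0.54, adjusted p = 0.011) and was above the isotype mean in 6 of 6 tumours. Cd74, the invariant chain, rose by 1.91 on the log2 scale (SE 0.47, adjusted p = 0.0144, above the isotype mean in 6 of 6 tumours). The CD8 T cell coreceptor gene Cd8a rose 2.63-fold (log2 fold change 1.39, SE 0.33, adjusted p = 0.0136, 6 of 6), but it was not called after quantile normalisation or with Ptprc as a covariate, and its lowest value over the alternative settings was 0.73. Slc11a1, a metal ion transporter of macrophage phagosomes, had the lowest adjusted p, 0.00335 (log2 fold change 1.42, SE 0.25, 6 of 6 tumours). Among the 600 genes, limma called 74, of which 72 rose and 2 fell, and 211 had an unadjusted p under 0.05.

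Other genes with large rises in NP1867 tumours were Slamf7, a receptor of natural killer and myeloid cells (1.61), Il7r, the receptor chain for interleukin 7 (1.56), Abcg1 and Apoe, which handle cellular cholesterol (1.53 and 1.49), and Tpsab1, a mast cell tryptase (1.44). Ciita, the master regulator of class II transcription, rose by 1.49 and Irf4, a transcription factor of lymphocytes and dendritic cells, by 1.48. Csf3r, the receptor for granulocyte colony-stimulating factor, rose by 1.32. The 2 genes that fell were H60a, a ligand of the activating receptor NKG2D (log2 fold change -0.52, SE 0.17, adjusted p = 0.0472, below the isotype mean in 6 of 6 tumours), and C1qbp, a mitochondrial protein that binds complement C1q (log2 fold change -0.42, SE 0.13, adjusted p = 0.038, 6 of 6). H60a lost its call in 12 of 25 alternative settings (range -0.92 to -0.34) and C1qbp in 9 of 25 (range -0.76 to -0.24), both of them with Ptprc as a covariate and without NP1867 isotype tumour 26. The groups did not overlap for 25 of the 600 genes, 4.17%, where chance gives 0.216% on average. The genes move together, so this share can vary widely by chance, and its range over regroupings was not worked out. The pan-leukocyte gene Ptprc had a log2 fold change of 0.54 (SE 0.28, adjusted p = 0.159, above the isotype mean in 6 of 6 tumours). The cytotoxic effector genes Gzmb and Prf1 had values of 0.79 (SE 0.35, adjusted p = 0.12, 5 of 6 tumours) and 0.75 (SE 0.40, adjusted p = 0.168, 4 of 6). Foxp3, the transcription factor of regulatory T cells, had a value of 0.22 (SE 0.41, adjusted p = 0.689, 5 of 6 tumours), which turned to -0.12 after centring each tumour on its median and to -0.24 after quantile normalisation. In NP1867 anti-PD-1 tumour 67 Foxp3 was at 2.04, which is 3 counts, against 4.42 for the next tumour. This value near the floor lowers the group mean, so the size and sign of the Foxp3 change are uncertain.

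Of the 29 gene lists tested, 13 were higher under anti-PD-1 in NP1867 tumours by the fry test of limma, each with its mean score above the isotype mean in 6 of 6 tumours. The Th2, Th17, B cell, alternatively activated macrophage and complement lists also had 6 of 6 tumours above it, and did not pass. This count of tumours therefore does not set the passing lists apart. The MHC class II list had the largest mean log2 fold change, 1.39 (adjusted p = 0.00425; adjusted p = 0.761 with an estimated correlation). Of its 11 tested genes 8 rose, or 10 adjusted over the list alone, H2-Aa by 1.88, H2-Ab1 by 1.86 and H2-DMa, which loads peptide, by 1.30. The MHC class I list had a mean of 0.67 (adjusted p = 0.00425; adjusted p = 0.761 with an estimated correlation), with 6 of 15 genes higher, or 13 adjusted over the list alone. These included the peptide transporter Tap2 (0.86), the immunoproteasome subunits Psmb9 (0.98) and Psmb10 (0.91), the nonclassical class I gene H2-T23 (1.10) and the classical class I gene H2-K1 (0.58).

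The list of interferon-gamma response genes had a mean of 0.71, with 8 of 23 genes higher, or 14 adjusted over the list alone, among them the transcription factor Irf8 (0.93) and Cd274, which encodes the PD-1 ligand PD-L1 (1.07). The list of immune checkpoints and co-stimulation had a mean of 0.77, with 8 of 20 higher, or 11 adjusted over the list alone: Pdcd1, which encodes PD-1 (1.18), Lag3 (1.17), Ctla4 (1.12) and the co-stimulatory ligand Cd86 (0.93) were among them. The dendritic cell list had a mean of 0.77, with 4 of 12 higher, or 7 adjusted over the list alone, including Xcr1, a receptor of cross-presenting dendritic cells (1.08). The Th1 list had a mean of 0.73, with 3 of 13 higher, or 7 adjusted over the list alone: the interleukin 12 receptor chain Il12rb1 (1.23), Ifng (1.21) and Tnf (0.80). The list of mast cells, basophils and eosinophils had a mean of 0.99, with 3 of 7 higher, or 5 adjusted over the list alone, including the mast cell chymase Cma1 (1.11). The list of CD8 T cells and cytotoxic effectors had a mean of 0.80, with 2 of 10 higher, or 4 adjusted over the list alone. These 6 lists each had an adjusted p = 0.0141, and an adjusted p = 0.761 with an estimated correlation.

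The T cell list had a mean of 0.90 (adjusted p = 0.0161; adjusted p = 0.761 with an estimated correlation), with 5 of 12 genes higher, or 11 adjusted over the list alone, among them the T cell receptor signalling chains Cd3d (1.26), Cd3e (1.10) and Cd3g (1.03). The list of T cell attracting chemokines and receptors had a mean of 0.77 (adjusted p = 0.0235; adjusted p = 0.806 with an estimated correlation), with 2 of 15 higher, or 6 adjusted over the list alone, Ccl4 by 1.29. The natural killer list had a mean of 0.66 (adjusted p = 0.0339; adjusted p = 0.822 with an estimated correlation) and 1 of 11 genes higher, Il21r (1.27), or 2 adjusted over the list alone. The regulatory T cell list had a mean of 0.62 (adjusted p = 0.0444; adjusted p = 0.822 with an estimated correlation) and 1 of 7 genes higher, Ctla4, also 1 adjusted over the list alone. The list of inflammatory cytokines and NF-kB had a mean of 0.39 (adjusted p = 0.0235; adjusted p = 0.99 with an estimated correlation), which was 0.05 after centring and turned to -0.02 after quantile normalisation. Of its 23 genes 4 rose, or 6 adjusted over the list alone, including the NF-kB subunit Rel (0.60) and the NF-kB inhibitor Tnfaip3 (0.79). Both lost their call after centring and after quantile normalisation, in 5 and 9 of 25 settings altogether, with lowest values of 0.18 for Rel (highest adjusted p = 0.501) and 0.45 for Tnfaip3. By an exact permutation test of list scores 7 lists passed, namely both MHC lists, T cells, Th1, checkpoints, dendritic cells and mast cells, each above the isotype mean in 6 of 6 tumours. In camera with a preset correlation both MHC lists, T cells, Th1, checkpoints, dendritic cells and interferon-gamma response passed (adjusted p from 0.00268 to 0.0451). Proliferation (adjusted p = 0.0079) and endothelium (adjusted p = 0.0278) passed there as well, with means of -0.14 and 0.07.

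**Figure D2:**
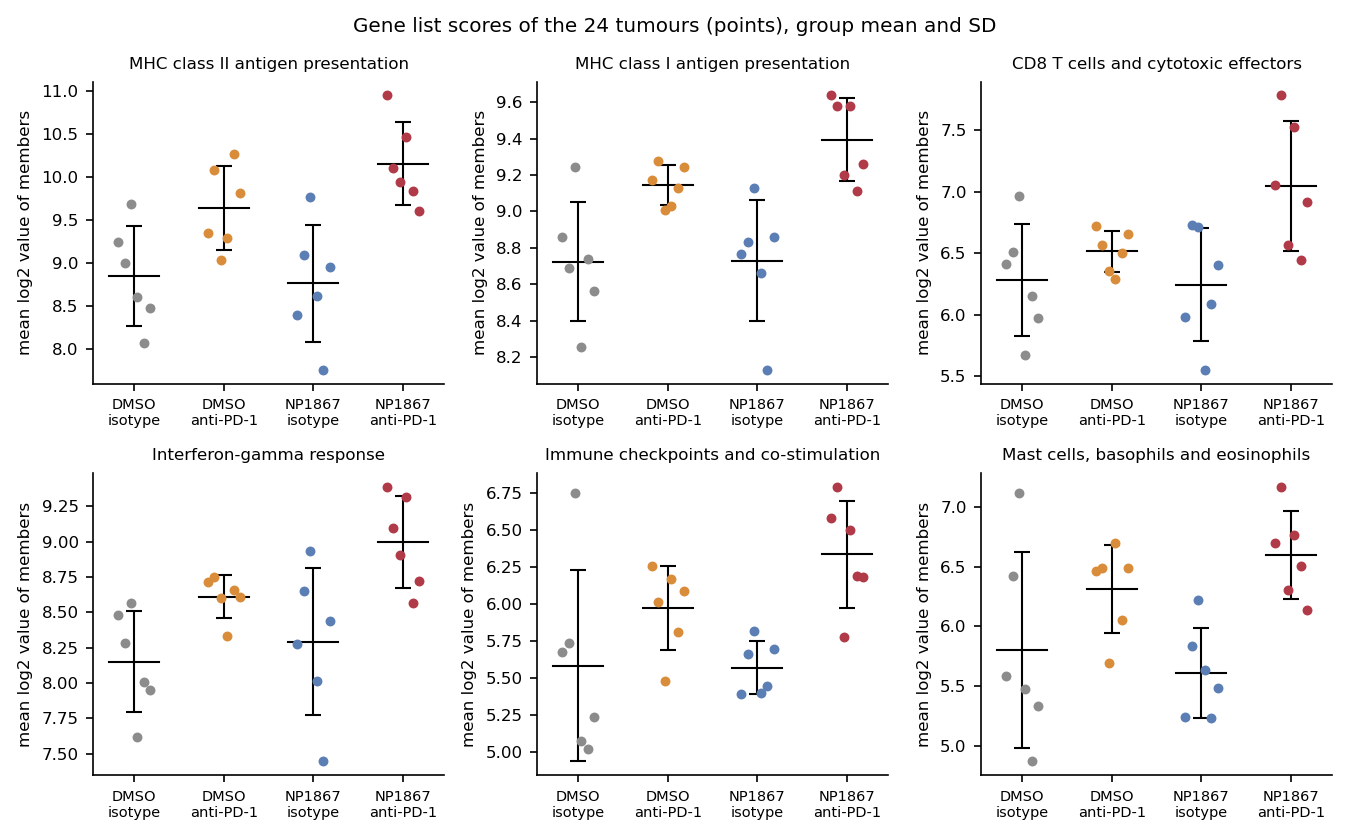
Scores of 6 gene lists (y, mean log2 value of the tested members) in the 4 groups; points are tumours (n = 6 per group), lines are means and bars SDs. The MHC class II score was 8.77 ± 0.68 in NP1867 isotype and 10.15 ± 0.49 in NP1867 anti-PD-1 tumours, and 8.85 ± 0.58 and 9.64 ± 0.49 in the DMSO groups.

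The median log2 fold change over all 600 genes was 0.43 in this comparison, 0.09 after centring each tumour on its median and -0.02 after quantile normalisation. The split of 72 rises and 2 falls became 38 and 40 after centring (40 of the 78 genes shared with the 74) and 23 and 32 after quantile normalisation. Of the 13 lists 9 still passed after centring, without the natural killer (mean 0.32, adjusted p = 0.0819), regulatory T cell (0.28, adjusted p = 0.288), checkpoint (0.43, adjusted p = 0.077) and NF-kB lists, and 3 after quantile normalisation (MHC class II, interferon-gamma response and dendritic cells), where the regulatory T cell mean was 0.08 and the natural killer mean 0.16; the proliferation list was lower under both (-0.48 and -0.50). With Ptprc as a covariate 16 genes passed, among them H2-Eb1, Cd74, H2-Aa, H2-Ab1, Slamf7 and Slc11a1, and of the 13 lists just 2 did, MHC class I (mean 0.45, adjusted p = 0.00665) and MHC class II (0.90, adjusted p = 0.00498), while the T cell list, with an adjusted p of 0.0949, and the interferon-gamma list, with 0.0559, did not. The count depended on single tumours: without 1 NP1867 isotype tumour it was 47 (tumour 10), 198 (tumour 47), 39 (tumour 49) or 27 (tumour 57), and without 1 NP1867 anti-PD-1 tumour 14 (tumour 78), 30 (tumour 30) or 27 (tumour 45). Without NP1867 isotype tumour 47, 21 lists passed.

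Single genes named for NP1867 tumours also depended on the setting. H2-Eb1, H2-Aa, H2-DMa, Slamf7, Slc11a1, Csf3r and Irf8 were called in all 25 settings; some of the other genes had 24, as the filter at 50 left them out. Cd74, H2-Ab1, Abcg1, Tpsab1, H2-T23 and Ccl4 lost their call in 1. Calls were lost in 13 settings for Tnf (lowest value 0.28) and Cma1 (0.66), in 12 for Apoe (0.80) and Ifng (0.46), in 11 for Cd3e (0.54) and H2-K1 (0.24), in 10 for Ctla4 (0.57), in 9 for Xcr1 (0.44), in 8 for Cd3g (0.54) and Psmb10 (0.57), in 7 for Cd86 (0.47), in 6 for Ciita (0.92) and Lag3 (0.54), in 5 for Irf4 (0.77), in 4 for Il21r (0.69) and in 3 for Pdcd1 (0.54). Il7r, Cd3d, Il12rb1, Cd274, Tap2 and Psmb9 lost theirs in 2. All of these rises kept their sign.

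The same question was asked of tumours from DMSO-treated cells. Lbp, which encodes the lipopolysaccharide-binding protein, had the largest change among the 10 genes with the lowest p, a log2 fold change of 2.30 (SE 0.68, adjusted p = 0.301, above the isotype mean in 6 of 6 tumours). Slc11a1 was at 0.89 (SE 0.25), the cytokine receptor chain Il2rg at 0.93 (SE 0.27), H2-DMa at 0.89 (SE 0.29) and Pdcd1 at 0.87 (SE 0.29), all with an adjusted p = 0.301 and above the isotype mean in 6 of 6 tumours. The transcription factors Creb1 (-0.38, SE 0.13) and Atf2 (-0.42, SE 0.14) were lower, with the same adjusted p = 0.301 and below the isotype mean in 6 of 6 tumours. None of these passed the threshold. Cd274 had a value of 0.76 (SE 0.26, adjusted p = 0.301), Cd8a of 0.59 (SE 0.33, adjusted p = 0.379) and Foxp3 of 0.95 (SE 0.41, adjusted p = 0.315), each above the isotype mean in 6 of 6 tumours, and Ptprc of 0.31 (SE 0.28, adjusted p = 0.557, 5 of 6). Gzmb was at -0.01 (SE 0.35, adjusted p = 0.992), and its sign turned under several settings. limma called 0 of 600 genes, voom on the recovered counts also 0, and 85 genes had an unadjusted p under 0.05. The groups did not overlap for 3 genes, 0.5%, where chance gives 0.216% on average.

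No gene list passed in DMSO tumours by fry (0 of 29, 3 with an unadjusted p under 0.05), by the exact permutation test or with an estimated correlation, and 3 passed in camera with a preset correlation. The MHC class I list had the lowest p, with a mean log2 fold change of 0.42 (adjusted p = 0.268, above the isotype mean in 6 of 6 tumours) and 0 of 15 genes past the threshold, also 0 adjusted over the list alone. The MHC class II list had a mean of 0.80 (adjusted p = 0.281, 6 of 6 tumours), with 0 of 11 genes past the threshold and 4 adjusted over the list alone. The T cell, CD8 T cell, natural killer and regulatory T cell lists were also above the isotype mean in 6 of 6 tumours. So were the Th1, interferon-gamma and T cell chemokine lists, while the checkpoint, dendritic cell, mast cell and NF-kB lists were in 5 of 6. The median over all genes was 0.23, and -0.02 after centring. Without DMSO isotype tumour 23, 9 lists passed and 0 genes. With weights for each tumour (limma's array weights) 273 genes and 24 lists passed, and without the 4 tumours of fewer than 200000 counts 14 lists by fry and 1 gene. Both MHC lists were among the 14, with means of 1.20 for class II and 0.56 for class I (adjusted p = 0.028 for each), against 1.39 and 0.67 in NP1867 tumours, and the difference between the responses in the class II list was then 0.19, where it was 0.59 with all tumours.

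The response to anti-PD-1 was then compared directly between NP1867 and DMSO tumours. The genes with the lowest p for the difference were Lilra5, a receptor of myeloid cells (difference in log2 fold change 1.23, SE 0.40), Il12rb1 (1.17, SE 0.41), Rel (0.56, SE 0.22), the natural killer receptor Klrc2 (1.72, SE 0.71) and Xcr1 (0.97, SE 0.44), each with an adjusted p = 0.995. limma called 0 of 600 genes for the difference, voom on the recovered counts 0, and 11 genes had an unadjusted p under 0.05. No list passed by fry (0 of 29) or with an estimated correlation, and 10 passed in camera with a preset correlation. The passing of genes and lists in NP1867 tumours and not in DMSO tumours is therefore not shown to be a difference between them. Across genes, which are not independent replicates, the log2 fold changes of both responses correlated with r = 0.719 and rho = 0.756, and 514 of 600 genes, 85.7%, had the same sign. Positive changes made up 438 of the 600 in DMSO and 462 in NP1867 tumours, so many genes would share a sign by that upward shift alone. None of 99 random regroupings of the tumours gave an r as high (range -0.718 to 0.664, median -0.026).

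**Figure D3:**
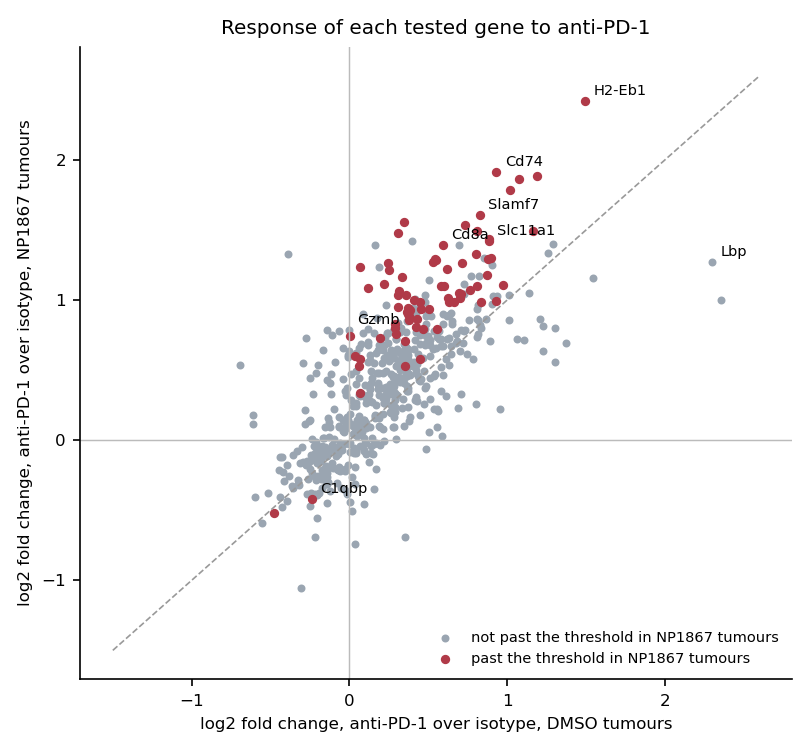
Log2 fold change of anti-PD-1 over isotype in DMSO tumours (x) and in NP1867 tumours (y) for the 600 tested genes; red points are the 74 genes that passed in NP1867 tumours and the dashed line marks equal changes. The values correlate with r = 0.719 across genes, and 0 genes passed for the difference.

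Averaged over both kinds of tumour, both MHC lists rose under anti-PD-1 by fry, and the 5 genes with the lowest p all rose. Camera with an estimated correlation, which asks whether a list moved more than the other genes of the panel, called neither list (adjusted p = 0.845 for each). Slc11a1 rose by 1.15 on the log2 scale (SE 0.17, adjusted p = 0.000414), Slamf7 by 1.22 (SE 0.21, adjusted p = 0.00129), H2-DMa by 1.10 (SE 0.20, adjusted p = 0.00275), Csf3r by 1.06 (SE 0.21, adjusted p = 0.00292) and H2-Eb1 by 1.96 (SE 0.38, adjusted p = 0.00292), each above the isotype mean of the same kind of tumour in 12 of 12 tumours. limma called 176 genes, 162 higher and 14 lower, and with Ptprc as a covariate 52 genes. After centring the split was 54 higher and 95 lower of 149, and after quantile normalisation 64 and 100 of 164.

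By fry 15 lists were higher in this average, and none with an estimated correlation (adjusted p from 0.845 to 0.965). After centring 10 lists passed, 6 of them higher. Lower after centring were endothelium (mean -0.195, against 0.1 as deposited), proliferation (-0.387 against -0.092) and apoptosis (-0.167 against 0.127). The mismatch repair and DNA damage list was also lower (-0.308 against -0.013). Its 3 tested genes were Atm, Cdkn1a and Trp53, none of them a mismatch repair gene. After quantile normalisation 11 lists passed, 9 of them higher, with proliferation and apoptosis lower. The interferon-gamma response list had 18 of 23 genes higher, or 20 adjusted over the list alone (mean 0.58, adjusted p = 0.00732; adjusted p = 0.845 with an estimated correlation). MHC class I had 12 of 15, or 13 adjusted over the list alone (mean 0.54, adjusted p = 0.00112; adjusted p = 0.845 with an estimated correlation). MHC class II had 8 of 11, also 8 adjusted over the list alone (mean 1.09, adjusted p = 0.00112; adjusted p = 0.845 with an estimated correlation). Complement, not called in either kind of tumour alone, had 12 of 19 genes higher and 1 lower, or 14 adjusted over the list alone (mean 0.67, adjusted p = 0.037, and adjusted p = 0.91 with an estimated correlation). By fry its mean was 0.37 after centring (adjusted p = 0.0691), 0.39 after quantile normalisation (adjusted p = 0.0332) and 0.27 with Ptprc as a covariate (adjusted p = 0.19). The mean of the inflammatory cytokine and NF-kB list, 0.29 (adjusted p = 0.0188; adjusted p = 0.965 with an estimated correlation), turned to -0.01 after centring. The gene count was 308, 97 or 116 without DMSO isotype tumour 23, 55 or 59, 103 without DMSO anti-PD-1 tumour 7, 117 without NP1867 isotype tumour 57 and 91 without NP1867 anti-PD-1 tumour 78. The list count was 23 without DMSO isotype tumour 6, DMSO isotype tumour 23 or NP1867 isotype tumour 47.

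The next comparisons asked how tumours from NP1867-treated cells differed from tumours from DMSO-treated cells under the same antibody. Under isotype, Spn, which encodes the sialoglycoprotein CD43 of leukocytes, was lower in NP1867 tumours at 8.0 ± 0.15 against 8.61 ± 0.13 (SD, n = 6 per group; log2 fold change -0.60, SE 0.11, adjusted p = 0.0067), below the DMSO mean in 6 of 6 tumours with no overlap between groups. Il1rn, the interleukin 1 receptor antagonist, was at 1.11 (SE 0.30, adjusted p = 0.291), Sigirr, an inhibitor of interleukin 1 and Toll-like receptor signalling, at -0.59 (SE 0.17, adjusted p = 0.358) and Il2ra, the alpha chain of the interleukin 2 receptor, at 1.07 (SE 0.32, adjusted p = 0.393), each on one side of the DMSO mean in 6 of 6 tumours. Cd8a was at -0.48 (SE 0.33, adjusted p = 0.692) and Ifng at -0.67 (SE 0.39, adjusted p = 0.638), each below the DMSO mean in 5 of 6 tumours. Spn was the 1 gene of 600 that limma called, and 46 had an unadjusted p under 0.05. It was not called after centring, after quantile normalisation or in a fit of these groups alone, where its adjusted p was 0.12, 0.0944 and 0.439 at log2 fold changes of -0.76, -0.79 and -0.60 (range over all alternatives -0.79 to -0.57). No list passed by fry (0 of 29, and 0 by the exact permutation test).

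Under anti-PD-1, Il1rn had the lowest adjusted p for NP1867 against DMSO tumours, 0.154 (log2 fold change 1.27, SE 0.30, above the DMSO mean in 6 of 6 tumours). Irf8 was at 0.78 (SE 0.20, adjusted p = 0.164), Sigirr at -0.64 (SE 0.17, adjusted p = 0.164) and Itgb3, an integrin chain, at 1.10 (SE 0.30, adjusted p = 0.172), each on one side of the DMSO mean in 6 of 6 tumours. The cytotoxic effector genes Gzmb (1.07, SE 0.35, adjusted p = 0.248) and Prf1 (1.09, SE 0.40, adjusted p = 0.278) were above the DMSO mean in 6 of 6 tumours and did not pass the threshold. limma called 0 of 600 genes, voom on the recovered counts 0, and 69 had an unadjusted p under 0.05. For 8 genes, 1.33%, the groups did not overlap, where chance gives 0.216% on average. Without DMSO anti-PD-1 tumour 74 there was 1 gene, Il1rn, and without NP1867 anti-PD-1 tumour 50 there were 2, Il1rn and Irf8. No list passed by fry (0 of 29, 2 with an unadjusted p under 0.05) or by the exact permutation test, while 10 passed with the log2 scaling factor as a covariate. The median over all genes was 0.27, and 0.03 after centring.

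Averaged over both antibodies, 12 genes differed between NP1867 and DMSO tumours. Higher in NP1867 tumours were Il1rn by 1.19 (SE 0.21, adjusted p = 0.00218), Il2ra by 1.11 (SE 0.23, adjusted p = 0.00852) and Txnip, a regulator of thioredoxin, by 0.54 (SE 0.12, adjusted p = 0.0119), each above the DMSO mean of the same antibody in 12 of 12 tumours. Lower were Spn (log2 fold change -0.47, SE 0.08, adjusted p = 0.00165) and Sigirr (-0.62, SE 0.12, adjusted p = 0.0051), each below that mean in 12 of 12 tumours. The other 7 are named after their values were seen. The kinase Jak1 (0.52) and the fungal receptor Clec7a (0.74) were higher in 12 of 12 tumours, and Itgb3 (0.91) and the cholesterol exporter Abca1 (0.92) in 11 of 12. The integrin chain Itgb4 (-0.82) was lower in 11 of 12 tumours, and the TWEAK receptor Tnfrsf12a (-0.41) and the MAP kinase phosphatase Dusp4 (-0.49) in 12 of 12, with adjusted p values for the 7 from 0.0163 to 0.0316. Over 36 alternative settings Spn, Il1rn, Sigirr and Il2ra were called in all, while Tnfrsf12a lost its call in 19, Clec7a in 18, Dusp4 in 15, Abca1 in 14, Itgb4 in 13, Itgb3 in 5, and Txnip and Jak1 in 3 each.

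These 12 genes, 7 higher and 5 lower, stood among 121 with an unadjusted p under 0.05, and no list passed by fry (0 of 29, 3 with an unadjusted p under 0.05). After centring 5 were higher and 10 lower of 15, and after quantile normalisation 5 and 11 of 16; the median over all genes was 0.18, and -0.02 after centring. With log2 total counts as a covariate 6 genes passed, 5 of them among the 12. The count was 26, 6 or 7 without DMSO isotype tumour 23, 59 or 64, 6 or 7 without DMSO anti-PD-1 tumour 11 or 13, 7 without NP1867 isotype tumour 47, and 7, 6 or 20 without NP1867 anti-PD-1 tumour 78, 45 or 50. Without DMSO isotype tumour 23, 2 lists passed, regulatory T cells and Th2 cytokines. Without the 4 low-count tumours 6 lists passed, with the log2 scaling factor as a covariate 4, and with array weights 3. The labels do not say how many separate cultures were kept with NP1867 or with DMSO, so these p values cover the spread between the tumours sampled and not that between cultures. Those tumours were chosen to lie near the mean volume of their group, so the spread over all tumours of a group was not measured.

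**Figure D4:**
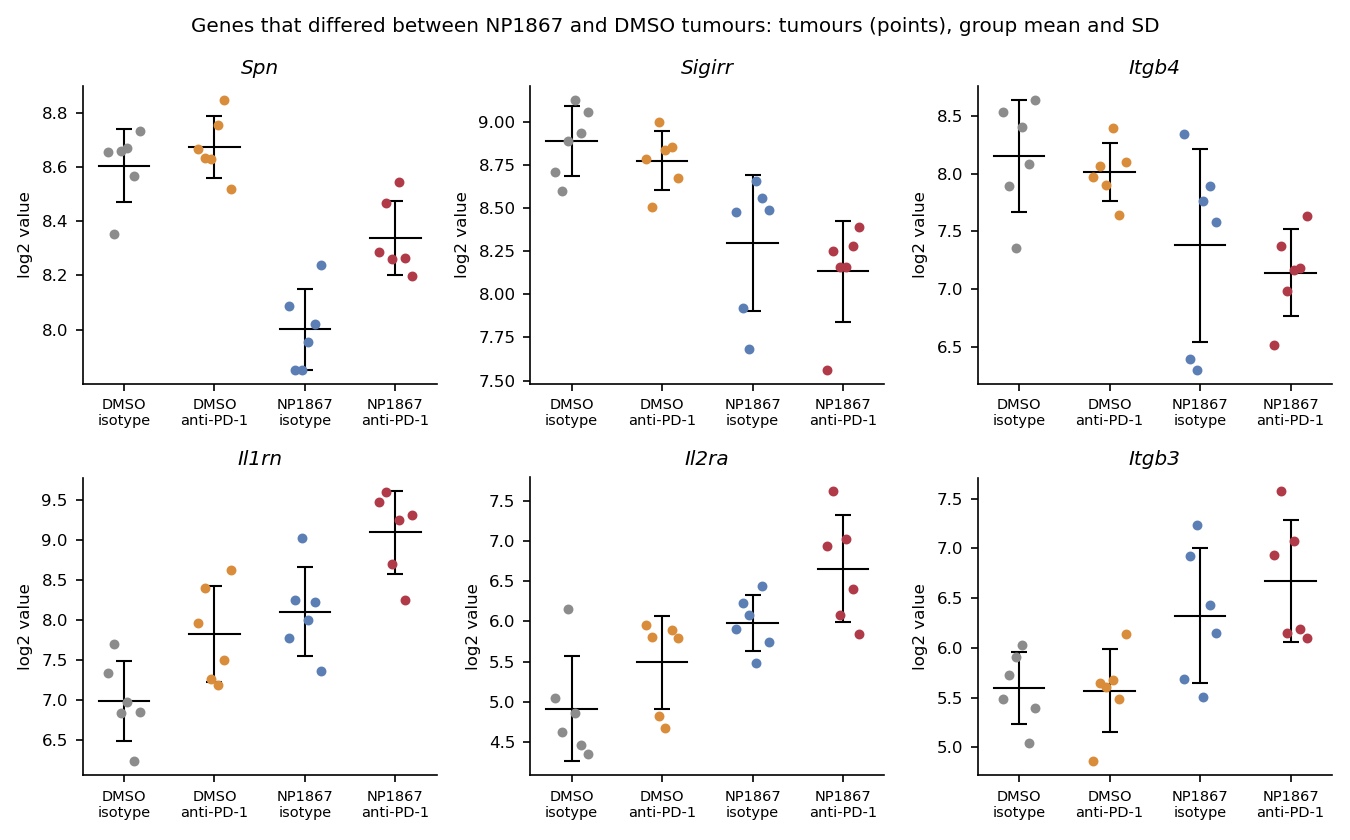
Log2 values (y) of 6 of the 12 genes that differed between NP1867 and DMSO tumours, in the 4 groups; points are tumours (n = 6 per group), lines are means and bars SDs. Under isotype the Spn values of the NP1867 tumours all lie below those of the DMSO tumours.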

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

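All tests of explanations in this part, and the fits with log2 total counts as a covariate or without low-count tumours, were chosen after the results were seen; centring, array weights and the Ptprc covariate were planned. The bounds for background in tumour 23, for low-count DMSO tumours and for the rises that lost their call were also changed after their values were known; by the bounds first written the first 2 explanations had counted as supported and the last as excluded, and all are left open here.

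In NP1867 tumours 72 of the 74 genes past the threshold rose under anti-PD-1. A single scaling factor per tumour that shifts every gene alike does not account for 38 of them, which still rose past the threshold after each tumour was centred on its median, while for the other 34, which lost their call as their median change went from 0.873 (SD 0.202, median SE 0.266) to 0.532 (SD 0.202, median SE 0.215), it cannot be told apart, because centring takes the same amount from every gene and these were chosen for lying high. All 72 still rose past the threshold with log2 total counts, which differed by 0.39 between these groups (exact permutation p = 0.201, n = 6 per group), as a covariate for depth (median 1.046 to 1.082). With Ptprc as a covariate for leukocyte content 16 of the rises stayed past the threshold, at a median of 0.998 (SD 0.276) against 1.314 (SD 0.415). The other 56 lost their call because their median change fell from 0.996 (SD 0.284, median SE 0.285) to 0.654 (SD 0.216, median SE 0.239). These 56 too were chosen for their rise. Ptprc is 1 gene that reads leukocyte content with error and not the share of each cell type, so leukocyte content stays open for all 72. How large a part of each rise is a shift shared by all genes also stays open, because no housekeeping genes are in the table. Of 100 splits of these tumours 3 gave as many genes (74, highest other 271) and 4 as many lists (13, highest other 26). These shares lie under 0.05 but rest on few splits and are not adjusted over the comparisons, so chance is not firmly excluded. The high counts of other splits also point to a structure of the samples. The first principal component held 50.4% of the variance, with the same sign for 508 of 600 genes.

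No gene passed between anti-PD-1 and isotype in DMSO tumours, against 74 in NP1867 tumours. A candidate explanation is background in low-count tumours: in DMSO isotype tumour 23, with the lowest total, the mean recovered count of the 150 genes below the filter was 9.8, within the range of the other tumours (4.1 to 25.2), where 2.7 would follow from their scaled level, but without tumour 23 still 0 genes passed (9 lists), and without the 4 low-count tumours, all of them DMSO tumours, 1 gene and 14 lists passed with fewer tumours. Array weights gave 273 genes in DMSO tumours, more than any of the other 99 splits (highest other 267, and 31 of them at least 1 gene), but also 267 in NP1867 tumours, none of which is among the low-count tumours. They gave the lowest weight to tumour 23 (0.126) and the next to NP1867 isotype tumour 47 (0.248), so low counts cannot be told apart from a spread among tumours that is not tied to depth. A different response in NP1867 tumours cannot be told apart, because 0 genes passed for the difference and its median over all genes was 0.132 as fitted and -0.032 without the 4 low-count tumours.

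Between NP1867 and DMSO tumours 12 genes passed in the average over antibodies. The low counts of 4 DMSO tumours do not account for the size of the 12 changes as a set. Without these tumours all 12 kept their direction with a median size of 0.688 against 0.676. Only 6 of them stayed past the threshold with fewer tumours. Some genes shrank, Txnip from 0.537 to 0.426 and Jak1 from 0.524 to 0.446, and others grew, such as Il2ra from 1.113 to 1.186. With log2 total counts as a covariate all 12 kept their direction at a median size of 0.641 and 5 stayed past the threshold. With Ptprc as a covariate 10 of the 12 stayed past the threshold. Clec7a went from 0.735 (SE 0.188) to 0.645 (SE 0.176, adjusted p = 0.0505) and Dusp4 from -0.492 (SE 0.126) to -0.431 (SE 0.116, adjusted p = 0.0504), and both lost their calls by smaller sizes. As Ptprc reads leukocyte content with error, leukocyte content is not excluded for any of the 12. Of 100 splits 2 gave as many genes (highest other 12), a share under 0.05 for tumours. It rests on few splits without adjustment over the comparisons, so chance is not firmly excluded. A difference between cultures that NP1867 did not cause stays open and untested, because the labels give no number of cultures.

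Among the remaining comparisons was anti-PD-1 averaged over both kinds of tumour. There 1 of 100 splits, the real one, gave as many genes (176, highest other 12) and lists (15, highest other 2). This share lies under 0.05 and is the lowest that 100 splits can give. It too is not adjusted over the comparisons, so chance is not firmly excluded. For NP1867 against DMSO under isotype 6 of 100 splits gave as many genes (1, highest other 96), so chance is not excluded for that count. The splits count any called gene, so they do not test Spn by itself. Where the real count was 0, all 100 splits reach it by construction and say nothing about chance; the highest counts of the other splits were then 92 genes and 15 lists for anti-PD-1 in DMSO tumours, 110 genes and 23 lists for the difference between the responses, 1 gene and 0 lists for NP1867 under anti-PD-1, 20 lists for NP1867 under isotype and 8 lists for NP1867 averaged over antibodies.

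A tumour stood far from the other 5 of its group in 22 of 448 groups of values examined (7 of 116 for list scores, 15 of 324 for named genes, 0 of 8 for depth), and chance gives about 1 in 20. The value given for each is the gap to the nearest tumour as a share of the range of the group. DMSO isotype tumour 23 was the highest of its group in 7 of them: the regulatory T cell score (0.77), Ccl4 (0.725), Cd86 (0.719), Creb1 (0.73), Psmb10 (0.686), Tap2 (0.672) and Tbx21 (0.658). DMSO isotype tumour 6 was the highest for the macrophage score (0.745), Arg1 (0.65) and C1qbp (0.689). DMSO isotype tumour 55 was the lowest for the type I interferon score (0.635). DMSO anti-PD-1 tumour 13 was the lowest for the T cell score (0.641), the regulatory T cell score (0.756), the inflammatory cytokine and NF-kB score (0.741) and Tap2 (0.725). DMSO anti-PD-1 tumour 37 was the lowest for the interferon-gamma score (0.645) and Klrk1 (0.641). NP1867 isotype tumour 26 was the highest for C1qbp (0.626), and NP1867 isotype tumour 57 the lowest for Psmb9 (0.782). Among NP1867 anti-PD-1 tumours, tumour 67 was the lowest for Foxp3 (0.719), at a log2 value of 2.04 against 4.42 for the next, tumour 78 for Sigirr (0.716) and tumour 48 for Tnfaip3 (0.724).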

How the results depend on the processing

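The fits with limma-voom, with the log2 scaling factor or log2 total counts as a covariate, with 10 added to the scaled counts or without the 4 low-count tumours were chosen after seeing the data. Rescaling to housekeeping genes and a covariate from them were not run because the table holds none, a pseudocount of 10, planned for linear values only, was run as one of those added fits, and the 2 count tools planned for recovered counts were not run, voom being used on them instead. No paired analysis was possible because the groups compared share at most 1 number in their sample titles. Numbers 47 and 74 occur in both kinds of tumour, and the titles do not say that they name the same mouse. Of 119 changes of named genes 59 were past the threshold, and 16 stayed past it under every alternative run: H2-Eb1, H2-Aa, H2-DMa, Slamf7, Slc11a1, Csf3r and Irf8 for anti-PD-1 in NP1867 tumours, Spn, Il1rn, Sigirr and Il2ra for NP1867 averaged over antibodies, and the 5 genes named for anti-PD-1 averaged over both kinds of tumour. Over 3188 values under alternatives, 2799 kept direction and side of the threshold, 293 lost the call, 81 gained one and 15 reversed. Low counts limit the 4 DMSO tumours, where 1 count is a large step. They also limit low genes in other tumours, such as Foxp3 with 3 counts in NP1867 anti-PD-1 tumour 67. Except where stated, the cause of a change was not tested.

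Anti-PD-1 in DMSO tumours (0 genes, 0 lists) gave 1 gene after centring, 1 after quantile normalisation, 273 genes and 24 lists with array weights, 1 gene and 14 lists without the low-count tumours, and 3 lists in camera with a preset correlation. In NP1867 tumours (74 genes, 13 lists) array weights gave 267 genes and 24 lists, Ptprc as a covariate 16 and 2, the scaling factor as a covariate 122 genes, total counts as a covariate 130 genes, the fit without the low-count tumours 139 genes, quantile normalisation 4 lists, camera with an estimated correlation 0 lists and the exact permutation test 7. NP1867 against DMSO under isotype (1 gene) gave 0 after centring, 0 after quantile normalisation, 0 in a fit of these groups alone, 13 with array weights and 2 with Ptprc as a covariate. Under anti-PD-1 (0 lists) the scaling factor as a covariate gave 10 lists. The difference between the responses (0 lists) gave 10 in camera with a preset correlation. NP1867 averaged over antibodies (12 genes, 0 lists) gave 70 genes and 3 lists with array weights, 27 and 4 with the scaling factor as a covariate, 6 genes with total counts as a covariate, and 1 list with quantile normalisation, 1 with the filter at 50 and 6 without the low-count tumours. Anti-PD-1 averaged over both kinds of tumour (176 genes, 15 lists) gave 404 and 26 with array weights, 52 and 3 with Ptprc as a covariate, 318 and 26 without the low-count tumours, 0 lists in camera with an estimated correlation and 6 with a preset one. The correlation of both responses (0.719) was 0.606 without a filter, 0.803 with the filter at 50, 0.788 with array weights and 0.548 with Ptprc as a covariate.

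Leaving out each tumour in turn, anti-PD-1 gave 0 to 9 lists in DMSO tumours (9 without isotype 23), 14 to 198 genes (14 without anti-PD-1 tumour 78, 198 without isotype 47) and 9 to 21 lists (21 without isotype 47) in NP1867 tumours, and 91 to 308 genes and 14 to 23 lists in the average. NP1867 gave 0 to 2 genes under anti-PD-1 (2 without NP1867 tumour 50), and 6 to 26 genes and 0 to 2 lists in the average (26 and 2 without DMSO isotype 23). The correlation ran from 0.641 to 0.805. Foxp3 in NP1867 tumours (0.219) reversed to -0.122 after centring, -0.236 after quantile normalisation, -0.094 with array weights and -0.118 with Ptprc as a covariate. Gzmb in DMSO tumours (-0.006) reversed to 0.209 with array weights, 0.029 with voom, 0.007 with the scaling factor and 0.01 with total counts as a covariate and 0.101 without the low-count tumours, and ran from -0.129 to 0.121 with 1 tumour left out.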

Other observations

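The test in this part was chosen after the results were seen. Of the 5 genes lower in NP1867 than in DMSO tumours, 4 also fell with Ptprc among tumours of the same group. Over 24 tumours, with group means removed and 5 relations tested by permutation, Tnfrsf12a had r = -0.82 (p = 3e-05, adjusted p = 0.00015; rho = -0.83, p = 2e-05, adjusted p = 0.0001), Sigirr r = -0.79 (p = 9e-05, adjusted p = 0.000225; rho = -0.74, p = 0.00018, adjusted p = 0.00045) and Itgb4, an integrin chain of epithelial cells, r = -0.70 (p = 0.0009, adjusted p = 0.0015; rho = -0.68, p = 0.00102, adjusted p = 0.0017). Dusp4 had r = -0.45 (p = 0.0317, adjusted p = 0.0396), and its rho of -0.43 did not pass (p = 0.0485, adjusted p = 0.0606). Spn, whose product CD43 is known from leukocytes, had r = -0.17 (p = 0.472, adjusted p = 0.472; rho = -0.16, p = 0.484, adjusted p = 0.484). Spn thus did not rise with Ptprc, and these values do not show that its signal came from leukocytes. Without the 2 tumours farthest from the median of Ptprc the r values were -0.79, -0.75, -0.62, -0.44 and -0.08. The r values with Ptprc ran from 0.13 to 0.89 over the 12 genes of the T cell list and from 0.03 to 0.90 over 22 of macrophages and monocytes, but from -0.78 to 0.71 over 7 epithelial and carcinoma cell markers and from -0.53 to 0.45 over 6 proliferation genes, which go both ways and decide nothing. The relations of these 4 of 5 genes allow expression mainly outside the leukocytes of the tumour, which may include the implanted carcinoma cells, but do not establish it. The share of the 600 tested genes that fall with Ptprc was not worked out. The 5 genes were chosen for being lower in a comparison where 470 of 600 genes were higher, so the count of 4 has no reference. The panel measured whole tumours, so the cells that express these genes were not observed.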
